A study of Rattus norvegicus with 6 samples.

How the data were processed

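RNA sequencing measured gene expression in rat liver collected on day 14 after liver trauma. The wound had been dressed with AKOC in 3 samples and with Quik-clot, the control dressing, in the other 3. No uninjured liver is among these samples. Groups and replicate numbers were taken from the sample labels.

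Read counts per gene were deposited by the authors as whole numbers without normalization, and a second deposited table gives FPKM (fragments scaled to transcript length and to sequencing depth) for the same genes and samples. Trimming with fastp, alignment with HISAT2 and counting with HTSeq, on the mRatBN7.2 rat genome build, are named in the submitters' processing notes. Their versions, annotation, strand setting and parameters are not given in the sources used here, nor is the way FPKM was computed. The deposited FPKM equal the count divided by transcript length and by the library's total count, with a largest relative error of 8.58e-07, so both tables hold the same measurement. No coordinates are given, because the reference gene table belongs to the GRCr8 assembly and the authors' build differs. Reads of near-identical genes (haemoglobin chains, RT1 genes, the Cyp2c and Mup families, Scd paralogs) and of overlapping antisense genes may have been split or pooled by the counting, so values for single members of these families are uncertain.

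The table holds 20104 genes. Total counts ran from 40402312 (AKOC replicate 3) to 41455378 (AKOC replicate 2), a 1.026-fold range, so depth differed little between libraries. The filterByExpr function of edgeR, with a minimum count of 10 and a minimum total of 15, kept 13872 genes, of which 13167 are protein-coding. Library sizes were scaled by the trimmed mean of M values (TMM), with factors from 0.902 to 1.12. Levels are given as CPM, counts scaled to 1e6 per library, after this scaling. Log2 CPM for principal components and list medians used a prior count of 2.

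The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts, two-sided, with the dressing as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of its F statistic. The biological coefficient of variation was 27.2% and the prior degrees of freedom 3.19. Nothing in the labels says whether the samples of a dressing came from separate animals, so p-values measure the spread between these samples, which may be technical. No pair of libraries in a group agreed within sampling noise. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1.

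The 47 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover inflammation, immune and other cell types, matrix and vessels, hepatocyte functions, metabolism, stress, proliferation and the circadian clock. For each list the number of members past the threshold was counted over all genes and again adjusted over the list alone. Lists with at least 5 measured members, 43 in all, were tested against the other genes with camera (limma 3.58.1; preset inter-gene correlation 0.01; Benjamini-Hochberg over the lists). A list was called at an adjusted p under 0.05. Camera with an estimated correlation and fry were run as alternatives.

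Named genes follow a rule with several parts. Up to 12 called genes per direction with the largest log2 fold change were to be named, with an established symbol, a mean of at least 1 CPM and no overlap between groups. Where fewer than 5 passed, the genes of smallest unadjusted p under the same conditions filled up to 5 and are given as not past the threshold. Of each list, up to 4 members past the threshold were named, and of a called list up to 4 of smallest unadjusted p. A fixed panel is always given: Tnf, Il1b, Il6, Il10, Tgfb1, Ccl2, Cd68, Mrc1, Cd163, S100a9, Acta2, Col1a1, Col3a1, Timp1, Mki67 and Alb. Members of the lists that bear on RNA quality, other cell types, collection time or sex may also be named. Further members of these lists, named below as values, were chosen after their values were seen.

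The alternatives were DESeq2 1.42.0, limma-voom with sample weights, the legacy quasi-likelihood method, median-of-ratios size factors, library totals only, other filters, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, other thresholds, the replicate number as a block, and leaving out each library. KEGG pathways from the deposited annotation, mitochondrially encoded genes under the symbols of the table and a length correction were added after seeing the data.

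The tests were checked on simulated counts for this comparison, with 13872 genes of which 200 were changed. The edgeR test recovered 39% of genes changed 2-fold, 88% of those changed 4-fold and 94% of those changed 8-fold, with 9 false calls, and made 0 calls where nothing changed. DESeq2 recovered 68%, 98% and 100%, with 51 false calls, and made 24 calls where nothing changed. The changed genes had a mean of at least 1 CPM, and counts were drawn with the fitted dispersion of each gene. In the real libraries edgeR called neither Scd, at 39.1-fold, nor Pnpla5, at 222-fold. These shares therefore do not carry over to the data, and 0 calls do not exclude large changes. Camera called the list raised 1.5-fold and 0 of 40 unchanged lists, but the simulated genes were independent of each other, which real genes are not. Figures were drawn with matplotlib 3.10.9.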

Results

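Livers of rats were sampled 14 days after a trauma that had been covered with either of 2 haemostatic dressings. AKOC, an abbreviation the labels do not expand, belongs to a series on kaolin scales anchored on cotton. Quik-clot, a commercial haemostatic dressing, was the control. Each dressing had 3 libraries, sequenced to totals between 40402312 and 41455378 counts. Albumin took from 7.02% of counts in Quik-clot replicate 1 to 11.7% in AKOC replicate 3. Mitochondrially encoded transcripts took 10.97%, 8.32% and 6.12% in the Quik-clot libraries and 8.23%, 8.91% and 9.18% in the AKOC libraries.

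The AKOC libraries resembled each other more closely than the Quik-clot libraries did. Spearman correlations of log2 CPM across genes were 0.979 to 0.982 within AKOC, 0.971 to 0.975 within Quik-clot and 0.960 to 0.979 between them. Quik-clot replicate 2 lay nearer to AKOC replicates 1, 2 and 3 (0.9795, 0.9767 and 0.97229) than to Quik-clot replicates 1 and 3 (0.97225 and 0.9713). The libraries thus did not group by dressing alone. The first principal component held 34.3% of the variance and placed the AKOC libraries at 21.5, 19.1 and 40.6 and the Quik-clot libraries at -33.1, 3.8 and -51.8. Quik-clot replicate 3 had the highest acute phase list median (0.87, log2 CPM against the mean of all 6), followed by AKOC replicate 2 (0.37). A2m stood at 2403 CPM in that Quik-clot library against 5.29 to 91.5 CPM in the other libraries, and Lcn2 at 3167 CPM against 3.10 to 262 CPM.

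The genes with the smallest p-values included Chka, which encodes choline kinase, at 61.3 ± 13.3 CPM after AKOC and 19.8 ± 1.91 CPM after Quik-clot (mean ± SD, n = 3 per dressing, as for all levels here). Pnpla5, a lipid droplet lipase, averaged 18.3 ± 15.4 CPM after AKOC and 0.080 ± 0.058 CPM after Quik-clot, and the clock activator Bmal1 31.0 ± 9.09 and 7.96 ± 1.67 CPM. Lower after AKOC were Cyp1a1, a target of the aryl hydrocarbon receptor, at 0.796 ± 0.153 against 14.3 ± 12.2 CPM, and the clock output gene Dbp at 5.10 ± 2.80 against 23.5 ± 4.26 CPM. None of these passed the adjustment over all genes.

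The edgeR quasi-likelihood test called 0 genes higher and 0 lower, with a lowest Benjamini-Hochberg adjusted p of 0.181. At an unadjusted p under 0.05 it gave 1731 genes, 941 higher and 790 lower after AKOC, where 694 would be reached by chance. DESeq2 called 186 genes higher and 94 lower with the same adjustment, and limma-voom 0 in either direction. All 275 DESeq2 calls that edgeR also tested had the same direction and an unadjusted p under 0.05 there. Both tests used the same counts, so this lends the calls no separate support, and DESeq2 also made 24 calls in simulated data without any change. In 2548 genes (18.4%) the levels of the dressings did not overlap, against 10% by chance.

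The 10 genes named by the fixed rule had log2 fold changes, AKOC over Quik-clot, of 1.63 ± 0.18 (SE) for Chka, 7.80 ± 0.95 for Pnpla5, 1.38 ± 0.17 for Paqr9, 0.96 ± 0.12 for the alcohol dehydrogenase Adh7 and 1.96 ± 0.26 for Bmal1. On the other side were Cyp1a1 at -4.16 ± 0.62, Sybu at -3.39 ± 0.51, Mtss1 at -0.77 ± 0.12, the stress-induced Herpud1 at -0.67 ± 0.11 and Dbp at -2.20 ± 0.37. Without AKOC replicate 1, edgeR called 6 genes higher, with Bmal1, Chka and Pnpla5 among them, and 4 lower, with Dbp, Per3 and Nr1d2 among them. Without Quik-clot replicate 2 it called 12 higher, Paqr9 and Car3 included, and 6 lower, Igfbp2 included. Without AKOC replicate 2 it called Abhd3 and Chchd2l3 higher.

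Circadian clock genes were the list with the most members past the threshold. Of 21 measured, 3 were higher and 11 lower after AKOC when adjusted over the list alone, and 0 over all genes. The higher genes were the activators Bmal1, Npas2 (log2 fold change 4.34 ± 0.87; 9.03 ± 6.50 against 0.444 ± 0.286 CPM) and Clock (0.40 ± 0.14). The lower genes included Dbp, Tef (-0.83 ± 0.17), Per3 (-2.30 ± 0.53) and Nr1d2 (-1.47 ± 0.40), all outputs or repressors of the clock. AKOC replicate 1 lay nearer to the Quik-clot libraries than AKOC replicates 2 and 3, with Npas2 at 1.55 CPM against 12.3 and 13.3 CPM. Camera placed the list below other genes (adjusted p = 0.000611; adjusted p = 0.61 with an estimated correlation). Leaving out a library gave 5 to 14 members past the threshold adjusted over the list alone, the fewest without AKOC replicate 2, and 8 without Quik-clot replicate 1. Hours of collection are not in the labels.

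**Figure D1:**
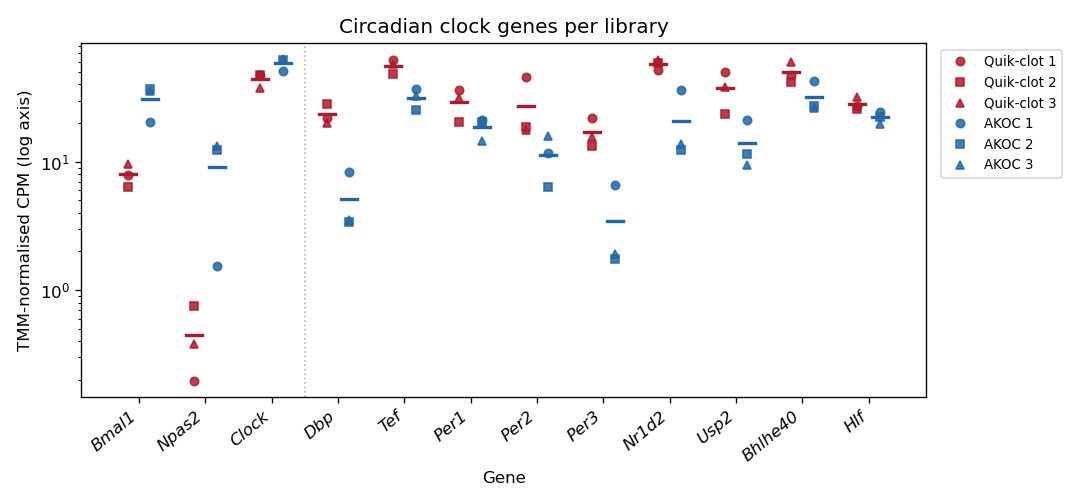
Levels of 12 circadian clock genes in each library, in TMM-normalised CPM on a log axis, with red for Quik-clot, blue for AKOC and a short line at the mean of 3 libraries. Bmal1, left of the dotted line with the other activators, averaged 31.0 CPM after AKOC against 7.96 CPM after Quik-clot, and Dbp 5.10 against 23.5 CPM.

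Genes of fatty acid and triglyceride synthesis were placed higher after AKOC by camera (adjusted p = 3.03e-08), but not with an estimated correlation (adjusted p = 0.61 with an estimated correlation). Of 27 measured members, 22 were positive and 5 negative, with 9 higher and 0 lower adjusted over the list alone, and 0 passed over all genes. Scd, the stearoyl-CoA desaturase, averaged 4821 ± 2663 CPM after AKOC against 123 ± 83.9 CPM (log2 fold change 5.29 ± 0.89). Liver pyruvate kinase Pklr had 1.82 ± 0.34, malic enzyme Me1 1.40 ± 0.37 and Pnpla3 3.32 ± 0.89, the last with 241 CPM in AKOC replicate 3 and 19.4 and 39.6 CPM in the others. Acacb, Gpam, Srebf1 and Acaca were also among them. Without Quik-clot replicate 1 the count adjusted over the list alone was 1. It was 3 without AKOC replicate 3 and 4 without AKOC replicate 2, while without Quik-clot replicate 3 there were 3 higher and 1 lower.

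Glucose metabolism genes lay on both sides. Adjusted over the list alone, 5 of 27 members were higher and 3 lower, with 0 over all genes. Besides Pklr, Pgk1 (0.79 ± 0.15), fructokinase Khk (0.59 ± 0.13), the glucokinase regulator Gckr (1.21 ± 0.31) and glycogen phosphorylase Pygl (0.92 ± 0.28) were higher. Pfkfb3 (-0.90 ± 0.24), the glucose transporter Slc2a2 (-0.58 ± 0.16) and glycogen synthase Gys2 (-0.58 ± 0.16) were lower. The list had a median log2 fold change of -0.007, a mean of 0.07 and an upward camera test that was not called (adjusted p = 0.153). It was called higher without AKOC replicate 1 (adjusted p = 0.0383) and without Quik-clot replicate 3 (adjusted p = 0.0230). No member passed adjusted over the list alone without Quik-clot replicate 3, AKOC replicate 2 or AKOC replicate 3, and 3 higher and 1 lower did without Quik-clot replicate 1. Without AKOC replicate 1 there were 5 higher and 0 lower.

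**Figure D2:**
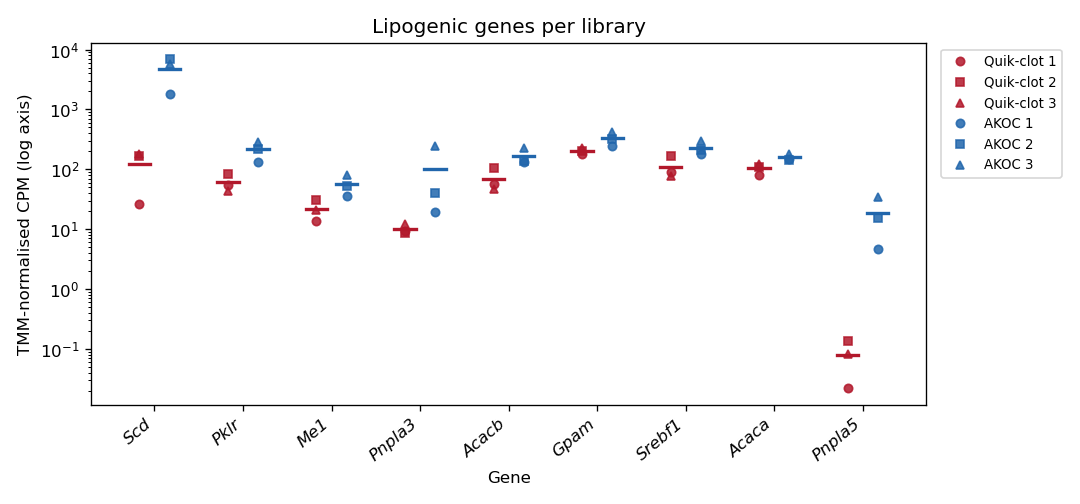
Levels of 8 lipogenic genes past the threshold adjusted over their list alone, and of Pnpla5, in each library (TMM-normalised CPM, log axis), with red for Quik-clot, blue for AKOC and a short line at the mean of 3 libraries. Scd averaged 4821 CPM after AKOC and 123 CPM after Quik-clot.

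All 34 measured nuclear genes of oxidative phosphorylation had positive log2 fold changes, with a median of 0.30. At an unadjusted p under 0.05 there were 19 higher, among them Uqcrc1 (0.45 ± 0.10), Ndufv1 (0.36 ± 0.09), Ndufv2 (0.43 ± 0.11) and Atp5po (0.43 ± 0.11), but 0 passed over all genes or adjusted over the list alone. The count adjusted over the list alone was 16 higher without Quik-clot replicate 2, 10 without AKOC replicate 1, 9 with DESeq2 and 6 with limma-voom. The camera adjusted p was 3.03e-08 (adjusted p = 0.61 with an estimated correlation). None of the fixed symbols for mitochondrially encoded genes occurred in the table. Under the symbols it uses, 13 were measured, 10 of them positive, with a median of 0.11 and an unadjusted camera p of 0.182.

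Cholesterol synthesis genes were placed lower by camera (adjusted p = 0.000106; adjusted p = 0.6205 with an estimated correlation), with 21 of 26 members negative and 0 past the threshold over all genes or adjusted over the list alone. Lss had a log2 fold change of -1.36 ± 0.39, Hsd17b7 -1.22 ± 0.36 and Srebf2 -0.48 ± 0.17. Lower adjusted over the list alone were 7 cholesterol genes without AKOC replicate 1, 1 without Quik-clot replicate 1 and 3 with DESeq2. The list median of AKOC replicate 1 (0.22) lay above those of Quik-clot replicates 1 and 2 (0.09 and 0.09). Hepatocyte transcription factors and identity genes were also placed lower (adjusted p = 0.00063; adjusted p = 0.61 with an estimated correlation), again with 0 members past either threshold. Of 20 measured, 14 were negative, such as Arg1 (-0.67 ± 0.18), Foxa3 (-0.68 ± 0.18), Nr1i2 (-0.66 ± 0.18) and Asl (-1.04 ± 0.32). There were 4 identity genes lower adjusted over the list alone without Quik-clot replicate 2 and 1 without AKOC replicate 1. The count was 7 lower with DESeq2, 5 with library totals only and 4 each with limma-voom and with no filter. Bile acid genes (24 measured, 18 negative, 0 past either threshold) had a camera adjusted p of 0.0291 (adjusted p = 0.61 with an estimated correlation), with Cyp8b1 at -0.96 ± 0.27, Slc10a1 at -0.35 ± 0.15, Slc27a5 at -0.54 ± 0.25 and Abcc3 at -0.83 ± 0.38. A single bile acid gene was lower adjusted over the list alone without AKOC replicate 1. The list lost its call without AKOC replicate 2 (adjusted p = 0.148) or AKOC replicate 3 (adjusted p = 0.0748).

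Secretory proteins that fall in an acute phase response were placed higher (adjusted p = 0.0129; adjusted p = 0.6205 with an estimated correlation), with 14 of 18 members positive and 0 past either threshold. Apoa4 had 1.58 ± 0.43, Serpina6 1.02 ± 0.44, Ttr 0.70 ± 0.35 and Mup4 3.26 ± 1.64, and the call ended without AKOC replicate 3 (adjusted p = 0.0933). Mup4 was low and overlapped between dressings, at 0.044, 1.146 and 0 CPM after Quik-clot and 9.025, 0.053 and 2.529 CPM after AKOC. Without Quik-clot replicate 2, 1 member was higher and 1 lower adjusted over the list alone, and without Quik-clot replicate 3, 1 was higher. Alb, which encodes albumin, averaged 96174 ± 24861 CPM after AKOC and 74320 ± 14253 CPM after Quik-clot. Acute phase proteins themselves were not called (22 measured, 18 negative, median -0.17, mean -0.62, adjusted p = 0.274), but were without Quik-clot replicate 1 (adjusted p = 0.00618) or AKOC replicate 2 (adjusted p = 0.0117). Among 37 measured genes of drug metabolism, Cyp2c7 (1.68 ± 0.34) was higher and Cyp1a1 and the P450 reductase Por (-1.20 ± 0.27) were lower adjusted over the list alone, with 0 over all genes. Adjusted over the list alone, 0 passed without AKOC replicate 2, and 5 higher and 6 lower did without Quik-clot replicate 2. That list had a median of 0.07, a mean of -0.20 and a downward camera test (adjusted p = 0.385; 0.0222 without Quik-clot replicate 3). Fatty acid oxidation genes had a median of 0.03, a mean of 0.03 and a downward test (35 measured, adjusted p = 0.908), with 0 past either threshold, though 2 were higher and 4 lower adjusted over the list alone without Quik-clot replicate 2 and 1 higher without Quik-clot replicate 1. With DESeq2 there were 1 higher and 3 lower.

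Among the inflammatory and immune lists, 5 were placed lower after AKOC by camera, though not with an estimated correlation, and without any member past the threshold over all genes or adjusted over its list alone. Of 13 anti-inflammatory and alternative-activation genes all 13 were negative (camera adjusted p = 0.00026; adjusted p = 0.61 with an estimated correlation), such as Mertk (-0.54 ± 0.15), the scavenger receptor Cd163 (-0.51 ± 0.15), Il4r (-0.31 ± 0.10) and the mannose receptor Mrc1 (-0.40 ± 0.13). Of 10 pro-inflammatory genes 9 were negative (adjusted p = 0.0051; adjusted p = 0.61 with an estimated correlation), with Il1a at -0.63 ± 0.19, Csf1 at -0.38 ± 0.15, Il33 at -0.55 ± 0.24 and Tnf at -1.20 ± 0.53. Of 21 macrophage and Kupffer cell markers 18 were negative (adjusted p = 0.000757; adjusted p = 0.6205 with an estimated correlation), with Cd14 at -0.72 ± 0.17 and Csf1r at -0.59 ± 0.23.

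T and NK cell markers (15 of 16 negative) had a camera adjusted p of 0.0051 (adjusted p = 0.65 with an estimated correlation), and Cd247 stood at -1.49 ± 0.42, Gzma at -1.19 ± 0.47, Prf1 at -1.001 ± 0.41 and Nkg7 at -1.03 ± 0.49. Antigen presentation genes (16 of 18 negative) had 0.00153 (adjusted p = 0.61 with an estimated correlation), and RT1-Da stood at -1.13 ± 0.40, Cd74 at -0.9998 ± 0.37, RT1-Db1 at -1.24 ± 0.48 and RT1-Bb at -1.59 ± 0.65. Quik-clot replicate 2 had the highest list medians for T and NK cells (1.07) and antigen presentation (0.85), with Gzma at 14.0 CPM against 3.08 to 4.30 CPM, while RT1-Bb was as high in Quik-clot replicate 3 (29.4 against 29.2 CPM). Without it, the adjusted p was 0.673 for T and NK cells, 0.168 for macrophages, 0.133 for antigen presentation and 0.0715 for pro-inflammatory genes, and 0.00225 for the anti-inflammatory genes. Without AKOC replicate 3 the calls for T and NK cells, macrophages and pro-inflammatory genes also ended (adjusted p = 0.0748, 0.0632 and 0.0748), and without AKOC replicate 1 that for T and NK cells (adjusted p = 0.0596).

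Of the pro-inflammatory genes 3 were lower adjusted over the list alone without AKOC replicate 1, as were 3 antigen presentation genes without Quik-clot replicate 1. With DESeq2 there were 1 pro-inflammatory, 2 anti-inflammatory, 2 macrophage and 4 antigen presentation genes lower.

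Single genes of the fixed panel did not pass over all genes. Tnf averaged 0.180 ± 0.086 CPM after AKOC and 0.421 ± 0.088 CPM after Quik-clot, Il1b 5.48 ± 2.504 and 8.94 ± 2.11 CPM, Il10 0.294 ± 0.092 and 0.655 ± 0.535 CPM, and Tgfb1 9.75 ± 0.66 and 11.4 ± 1.28 CPM. Cd68 stood at 39.6 ± 9.97 and 57.8 ± 16.7 CPM and Ccl2 at 0.289 ± 0.234 and 0.242 ± 0.164 CPM. The neutrophil gene S100a9 ranged from 3.29 to 55.9 CPM within Quik-clot alone, with a log2 fold change of -0.46 ± 0.94 that turned positive (1.32) without Quik-clot replicate 3. Il6 had 1, 0 and 4 counts after Quik-clot and 0 in each AKOC library and was below the filter. Adjusted p for the tested panel genes ran from 0.312 (Cd163) to 0.931 (Alb) in edgeR.

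Other immune lists were not called. These were chemokines (19 measured, adjusted p = 0.712; median 0.01, mean -0.03, downward test), lipid-associated and foreign-body macrophages (14, adjusted p = 0.277), neutrophils (7, adjusted p = 0.652), mast cells and eosinophils (8, adjusted p = 0.355), B and plasma cells (11, adjusted p = 0.0868) and the interferon response (27, adjusted p = 0.292). Complement (25, adjusted p = 0.806), coagulation (30, adjusted p = 0.512) and platelet markers (5, adjusted p = 0.731) were not called either. The interferon list gained a call without Quik-clot replicate 2 (adjusted p = 0.0279) or AKOC replicate 3 (adjusted p = 0.00545). None of these 9 lists had a member past the threshold over all genes or adjusted over the list alone in edgeR with all libraries. For the lipid-associated macrophages, DESeq2 and limma-voom each gave 2 higher and 2 lower adjusted over the list alone. Leaving out Quik-clot replicate 3 gave 2 higher, Quik-clot replicate 2 or AKOC replicate 1 gave 1 each way and AKOC replicate 2 gave 1 lower. A single complement gene was higher without Quik-clot replicate 2, and a single interferon gene with DESeq2.

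**Figure D3:**
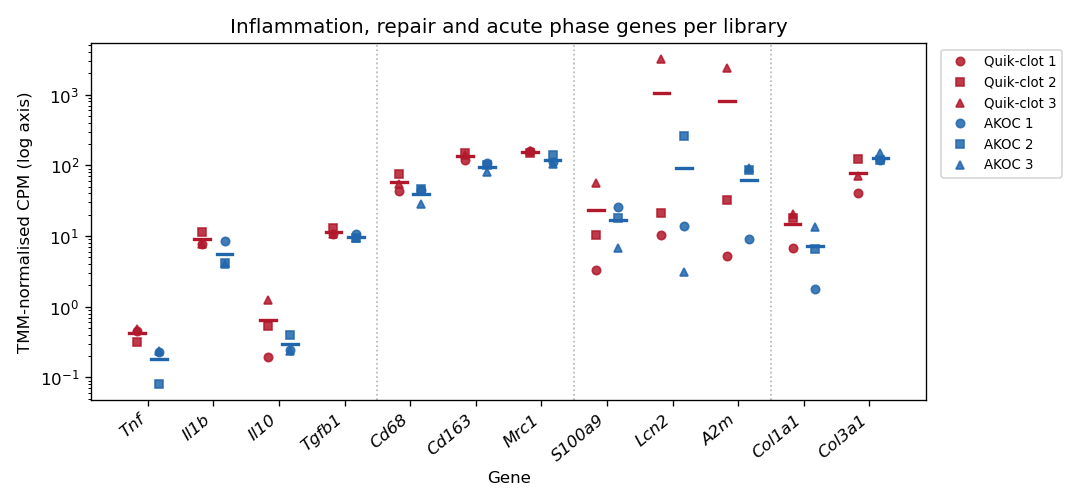
Levels of inflammatory, macrophage, acute phase and matrix genes in each library (TMM-normalised CPM, log axis), with red for Quik-clot, blue for AKOC and a short line at the mean of 3 libraries. A2m and Lcn2 reached 2403 and 3167 CPM in Quik-clot replicate 3.

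Collagens and extracellular matrix genes were placed higher by camera (29 measured, 19 positive, adjusted p = 0.0316; adjusted p = 0.6745 with an estimated correlation), with 0 members past either threshold. Col8a1 (1.16 ± 0.30), Lum (1.90 ± 0.57) and Bgn (0.72 ± 0.24) were positive and Postn (-3.76 ± 1.04) negative. Postn was low throughout, at 0.326, 1.88 and 2.053 CPM after Quik-clot and 0, 0.053 and 0.261 CPM after AKOC. The fibrillar collagens pointed in opposite directions, Col3a1 at 129 ± 17.9 CPM after AKOC against 78.6 ± 41.5 CPM and Col1a1 at 7.28 ± 5.85 against 14.95 ± 7.13 CPM. Acta2 averaged 4.97 ± 0.74 against 5.42 ± 0.64 CPM and Timp1 2.51 ± 0.23 against 3.70 ± 1.07 CPM. Adjusted over the list alone, 2 matrix genes were higher without Quik-clot replicate 2, and 4 higher and 1 lower with DESeq2. The matrix call ended without Quik-clot replicate 1 (adjusted p = 0.867) or AKOC replicate 3 (adjusted p = 0.62).

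Matrix remodelling enzymes (22 measured, adjusted p = 0.712), stellate cell markers (19, adjusted p = 0.0897) and growth factor signalling by TGF-beta, PDGF and CTGF (19, adjusted p = 0.355) were not called. The stellate list gained a call without Quik-clot replicate 2 or 3 (adjusted p = 0.04925 and 0.0316), and 1 member was higher adjusted over the list alone without Quik-clot replicate 2. Inhba, an activin subunit in the last list, was higher adjusted over the list alone (1.49 ± 0.29), with 0 over all genes, and did not pass without any 1 of the Quik-clot libraries. Endothelial markers were placed lower (15 of 19 negative, adjusted p = 0.03505; adjusted p = 0.6205 with an estimated correlation), with 0 past either threshold and Flt4 at -0.71 ± 0.23, Lyve1 at -0.30 ± 0.10, Pecam1 at -0.26 ± 0.11 and Kdr at -0.27 ± 0.13. Angiogenesis and hypoxia genes were placed lower too (12 of 18 negative, adjusted p = 0.0316; adjusted p = 0.6205 with an estimated correlation). In that list Pdk1, a kinase that inhibits pyruvate dehydrogenase, was higher adjusted over the list alone (0.98 ± 0.17), with 0 over all genes, though not without Quik-clot replicate 1 or AKOC replicate 2. Lower by the same adjustment were 5 members without Quik-clot replicate 2, 2 without AKOC replicate 3 and 4 with DESeq2. Ero1a (-0.46 ± 0.12), Hif1a (-0.32 ± 0.09) and Vegfa (-0.64 ± 0.20) were negative. A single endothelial gene was lower adjusted over the list alone without Quik-clot replicate 2. The endothelial call ended without Quik-clot replicate 1 or 3 or AKOC replicate 3 (adjusted p = 0.114, 0.18 and 0.137). The angiogenesis call ended without Quik-clot replicate 3 or any 1 of the AKOC libraries (adjusted p from 0.0515 to 0.24).

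Heme and iron genes were placed lower (17 of 24 negative, adjusted p = 0.0316; adjusted p = 0.61 with an estimated correlation). Adjusted over the list alone, 5 were lower and 1 higher, with 0 over all genes. The iron exporter Slc40a1 (-0.60 ± 0.13), the ferritin receptor Ncoa4 (-0.59 ± 0.15), heme oxygenase Hmox1 (-0.75 ± 0.20), Tfrc and Cd163 were lower, and ferrochelatase Fech (0.74 ± 0.17) was higher. The call ended without Quik-clot replicate 2 or 3 or AKOC replicate 3 (adjusted p = 0.057, 0.15 and 0.167). Adjusted over the list alone, 0 members passed without Quik-clot replicate 3 or any 1 of the AKOC libraries. Red cell transcripts were placed higher (12 of 13 positive, adjusted p = 1.28e-05; adjusted p = 0.61 with an estimated correlation), with 0 past either threshold and Hbb-bs at 2.67 ± 0.91, Hba-a3 at 1.54 ± 0.59, Epb42 at 1.07 ± 0.48 and Hemgn at 1.46 ± 0.88. Without Quik-clot replicate 3, 10 red cell members were higher adjusted over the list alone. The list median of that library (1.0, log2 CPM against the mean of all 6) lay above those of AKOC replicates 2 and 3 (0.55 and 0.86). These transcripts were lowest in Quik-clot replicate 1, where Hba-a1 stood at 24.2 CPM against 104 to 736 CPM in the other libraries.

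Heat shock genes were placed lower (10 of 13 negative, adjusted p = 0.0438; adjusted p = 0.624 with an estimated correlation). Adjusted over the list alone, the chaperones Hspa8 (-0.92 ± 0.24), Hsph1 (-0.53 ± 0.14) and Bag3 (-0.69 ± 0.20) were lower and Hspa4l (3.04 ± 0.78) was higher, with 0 over all genes. Immediate early genes were placed lower (15 of 19 negative, adjusted p = 0.0104; adjusted p = 0.65 with an estimated correlation), with 0 past either threshold and Ier3 at -0.81 ± 0.18, Zfp36 at -0.75 ± 0.22, Dusp1 at -1.38 ± 0.67 and Junb at -1.16 ± 0.58. Without Quik-clot replicate 2, 2 immediate early genes were lower adjusted over the list alone. Cell cycle genes were placed higher (23 of 33 positive, adjusted p = 0.0336; adjusted p = 0.6745 with an estimated correlation), with 0 past either threshold and Mcm6 at 0.73 ± 0.26, Rrm2 at 1.43 ± 0.52, Tyms at 0.34 ± 0.13 and Nusap1 at 1.47 ± 0.66. Mki67 went the other way at -0.41 ± 0.54. Heat shock lost its call without Quik-clot replicate 1, AKOC replicate 2 or AKOC replicate 3 (adjusted p = 0.386, 0.0729 and 0.0632), with 0 members past the threshold adjusted over the list alone in each case. Immediate early genes lost theirs without Quik-clot replicate 3 or AKOC replicate 3 (adjusted p = 0.6395 and 0.333). Cell cycle genes lost theirs without Quik-clot replicate 1 or 3 or AKOC replicate 1 or 2 (adjusted p = 0.588, 0.15, 0.113 and 0.0729).

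Herpud1 was lower adjusted over the list alone among 22 genes of the unfolded protein response, with 0 over all genes, and that list was not called (adjusted p = 0.155). Herpud1 did not pass without AKOC replicate 2 or 3, and the list gained a call without Quik-clot replicate 1 (adjusted p = 0.0198). The NRF2 targets (26, adjusted p = 0.0803), apoptosis and p53 targets (21, adjusted p = 0.292), ribosomal proteins (45, adjusted p = 0.151), cholangiocyte and progenitor markers (15, adjusted p = 0.1105) and adipocyte markers (7, adjusted p = 0.285) had no member past either threshold and were not called. Without Quik-clot replicate 1 or AKOC replicate 3 the NRF2 targets (adjusted p = 0.0264 and 0.0114) and the ribosomal proteins (adjusted p = 0.0278 and 0.0133) were called, the latter also without Quik-clot replicate 2 (adjusted p = 0.0430). For the NRF2 targets, 3 were higher adjusted over the list alone without AKOC replicate 1, 1 without Quik-clot replicate 1 or AKOC replicate 3 and 1 each way without Quik-clot replicate 2, against 5 higher and 1 lower with DESeq2. Apoptosis and p53 targets had 2 higher without AKOC replicate 2 and 3 each way with DESeq2. Cholangiocyte markers had 1 each way without Quik-clot replicate 2 or with DESeq2 and 1 lower without AKOC replicate 2, and adipocyte markers 1 lower without AKOC replicate 1. Of the tissues next to the liver, 3 mesothelial markers passed the filter and Gpm6a (1.33 ± 0.31) was higher adjusted over the list alone. Gpm6a had 301 to 1668 counts, while Rspo1 reached 57, Msln 35 and Upk3b and Wt1 7 in any library. Cela1 (1.27 ± 0.29) was the single pancreatic marker measured and the only p-value in its list. It had 122 to 582 counts, and the other pancreatic markers in the table at most 12. Neither Gpm6a nor Cela1 alone therefore marks its tissue here. No skeletal muscle marker passed the filter, the highest being Tnnc2 with 13 counts. Sex-biased hepatic and Y-linked genes were not called (13 measured, adjusted p = 0.0803). They gained a call without Quik-clot replicate 1 (adjusted p = 0.0298), Quik-clot replicate 2 (0.000179), AKOC replicate 1 (0.0216) or AKOC replicate 2 (0.00982). Without Quik-clot replicate 2, 5 members were higher and 1 lower adjusted over the list alone. The Y-linked genes Kdm5d, Eif2s3y and Uty were expressed in all 6 libraries.

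Camera in all called 6 lists higher and 14 lower of 43. With an estimated correlation, and with fry, 0 lists were called in either direction. Where not given above, DESeq2 counts adjusted over the list alone were 3 higher and 10 lower for the clock, 12 and 0 for lipogenesis, 8 and 3 for glucose metabolism and 4 and 7 for drug metabolism. They were 1 and 5 for heme and iron and for heat shock, 0 and 2 for immediate early genes, 1 and 1 for sex-biased genes, 0 and 1 for bile acids and 1 and 0 for secretory proteins. The mixed test of fry, which asks for change whatever its direction, was under 0.05 for 4 lists: lipid-associated macrophages and angiogenesis (adjusted p = 0.03475 for both), and glucose metabolism and apoptosis (adjusted p = 0.0399 for both). Other ways of dividing the 6 libraries into 3 and 3 gave 12 to 21 called lists with the preset correlation, so the number of called lists does not set the dressings apart. These divisions mix the dressings unevenly and keep part of any difference between them, so they do not exclude one either.

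**Figure D4:**
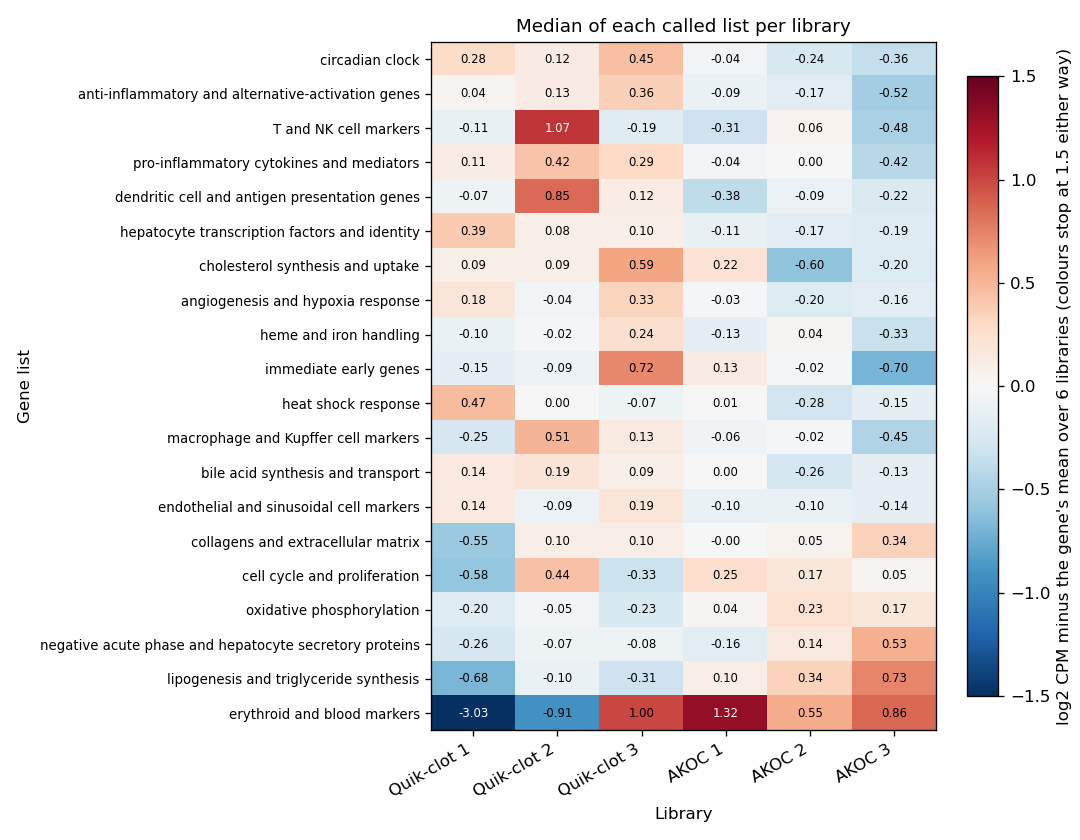
Median of each of the 20 lists called by camera in each library, as log2 CPM minus the gene's mean over the 6 libraries (red above, blue below). T and NK cell markers reached 1.07 in Quik-clot replicate 2, and red cell transcripts -3.03 in Quik-clot replicate 1.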

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

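Each alternative named here was chosen before the data were examined. Of 1793 values of named genes under the alternatives, 1783 kept their direction. The others belong to 3 genes: Ccl2 (-0.4222 without AKOC replicate 3 to 0.8366 without Quik-clot replicate 2, and -0.1942 without Quik-clot replicate 1), S100a9 (0.1932 with limma-voom, 0.08992 with limma-trend on log2(FPKM + 1) with or without the filter, 0.1561 with limma-trend on log2(FPKM + 0.1), 0.4213 with the replicate block, and -0.9786 without Quik-clot replicate 1 to 1.322 without Quik-clot replicate 3) and Mki67 (0.01838 with limma-voom, -0.7626 without Quik-clot replicate 1 to 0.5233 without Quik-clot replicate 2). The 0 genes called by edgeR, with 1731 at an unadjusted p under 0.05, became 186 higher and 94 lower with DESeq2. They became 234 higher and 159 lower at an unadjusted p under 0.05 and at least 2-fold. Leaving out a library gave 0 to 12 higher and 0 to 6 lower. With limma-voom, the legacy method, other size factors, other filters or log2 FPKM the count stayed at 0. The number of genes at an unadjusted p under 0.05 was 1126 with limma-trend on log2(FPKM + 1), 1149 with limma-trend on log2(FPKM + 0.1) and 1080 to 2460 without 1 library, the lowest without AKOC replicate 3 and the highest without Quik-clot replicate 2. Lists called higher numbered 6 to 9 and lower 6 to 15 without 1 library, against 6 and 14 with all, and 0 and 0 with an estimated correlation or fry. Of the 20 called lists, 7 kept their call without any 1 library: clock, lipogenesis, oxidative phosphorylation, red cells, cholesterol, anti-inflammatory genes and hepatocyte identity. The cause of these changes was not tested. With library totals only, the angiogenesis and heat shock lists lost their calls and the sex-biased list gained one. The filter at 1 CPM ended that of heat shock and added B and plasma cells. With no filter the stellate and sex-biased lists were added. Leaving out members shared between lists ended the call of heme and iron genes and added the NRF2 targets.

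With the replicate number as a replicate block, 1 gene was called higher (Pnpla5) and 0 lower, with 1317 at an unadjusted p under 0.05. Collagens lost their call, with 1 member lower over the list alone, and the NRF2 targets gained one. Samples with the same number did not deviate together (correlations of -0.072, -0.082 and -0.201), and samples with unlike numbers gave -0.096 to 0.174. With 3 samples per dressing these values cannot settle whether the numbers pair them.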

Other observations

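The tests of clock and lipogenic genes, of single libraries and of gene counts in other splits were chosen only after the results were seen, as were the KEGG pathways. Cyp2c12, a female-biased steroid hydroxylase, stood at 918, 97.0 and 283 CPM in the Quik-clot libraries and at 8.69, 17.3 and 74.7 CPM in the AKOC libraries (log2 fold change -3.69 ± 1.06). Male-biased Cyp2c11 stood at 140, 1695 and 118 CPM and at 1766, 767 and 3378 CPM (1.60 ± 1.07). Both belong to a family of similar genes. Hamp, the iron hormone hepcidin, had 822, 460 and 56.7 CPM after Quik-clot and 177, 63.8 and 27.2 CPM after AKOC (-2.32 ± 0.98), and the cell cycle inhibitor Cdkn1a 3.09, 1.28 and 7.67 CPM and 34.9, 8.57 and 16.3 CPM (2.32 ± 0.72). In edgeR none of these 4 genes passed over all genes or over its list alone, and the unadjusted p was 0.00989 for Cyp2c12, 0.178 for Cyp2c11, 0.0486 for Hamp and 0.0143 for Cdkn1a.

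Of 322 KEGG pathways camera called 27 higher and 13 lower with the preset correlation and 0 with an estimated one. Oxidative phosphorylation (median log2 fold change 0.216), degradation of branched-chain amino acids (0.275), pyruvate metabolism (0.254) and the citrate cycle (0.259) were among the higher ones. Genes of helper T cell differentiation (-0.282 for Th1 and Th2) and steroid biosynthesis (-0.359) were among the lower ones.

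The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. As many genes called by edgeR as in the real split (0) came from 10 of the 10 splits, the highest other count being 1. As many at an unadjusted p under 0.05 (1731) came from 1 split, the real one, with 941 as the highest other. As many called lists (20) came from 6 splits, with 21 as the highest other. As many clock genes adjusted over the list alone (14) came from 1 split, with 1 as the highest other, and as many lipogenic genes (9) from 1 split, also with 1. These lists were picked for their counts in the real split, so their comparison lends no support. Other splits, which each mix the dressings, gave up to 5 neutrophil and 5 sex-biased genes, where the real split gave 0. Summed over the lists, the count was 47 in the real split and at most 13 in another. DESeq2 called 280 genes in the real split and at most 70 in another.

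Clock genes differed in both directions between the dressings, with 8 of 21 positive and 13 negative. A different mix of cells or RNA was taken to move clock genes together. The median was 1.34 for a group of 4, the activators Bmal1, Npas2 and Clock and the repressor Cry1. It was -1.47 for a group of 11 outputs and repressors such as Dbp and Per3, a gap of 2.807. Both groups were formed after the values were seen and leave out other members of the list. The gap therefore cannot exclude such a mix. Collection at another hour of the day may account for the pattern. A clock index was the mean log2 CPM of the group with Bmal1 minus that of the group with Dbp. It was -1.58, -1.51 and -1.20 after Quik-clot and 0.31, 2.75 and 2.77 after AKOC. The difference was 3.37 (exact permutation test, two-sided p = 0.1, the smallest possible). The labels give no hour, so hour and dressing cannot be told apart, and a shift of the clock by the dressing stays open and untested.

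Camera placed lipogenic and oxidative phosphorylation genes higher after AKOC, though not with an estimated correlation (adjusted p = 0.6103 for both), with 9 of 27 and 0 of 34 members past the threshold over the list alone. More hepatocytes in the AKOC pieces would raise hepatocyte genes alike, but the identity list had a median log2 fold change of -0.4086 and the secretory list 0.36, with Alb at 96174 against 74320 CPM. Neither reached the lipogenic median of 0.72, which argues against that share as the whole cause of the lipogenic difference, and for oxidative phosphorylation it stays open. With each library's trend with length removed, the median difference of oxidative phosphorylation went from 0.303 to 0.2213, so that trend accounts for only part of it. This lay above all 10000 random lists matched on length and expression (95% of them between -0.094 and 0.133). Random members were drawn independently, while the genes of the list had an estimated correlation of 0.436. That band is therefore too narrow to weigh the remaining difference. Feeding before collection, which the labels do not give, and the dressing stay open and untested.

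Camera placed 5 inflammatory and immune lists lower after AKOC, though none with an estimated correlation (adjusted p = 0.6103 to 0.6498), and the interferon list was positive in 19 of 27 members. Without Quik-clot replicate 2, which may account for part of this, T and NK cell markers went from a median of -0.487 to 0.046 (camera adjusted p = 0.6734) and macrophage markers from -0.291 to -0.052 (0.1677). Antigen presentation genes went from -0.421 to -0.234 (0.1333), which leaves open how much that library contributes, and pro-inflammatory genes lost their call (0.07153), but leaving out AKOC replicate 3 also ended the calls of T and NK cell, macrophage and pro-inflammatory genes (0.07477, 0.06319 and 0.07477). Anti-inflammatory genes stayed called at a median of -0.435 against -0.511 (0.002253), which argues against that library as their whole source. The call itself does not set the dressings apart, since 4 of the 9 other splits also called this list, at a camera adjusted p down to 3.28e-05 against 0.00026. Those splits mix the dressings unevenly and keep part of any difference between them, so their calls do not exclude one either. An effect of the dressing stays open and untested.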
